A study of Mus musculus with 22 samples.

How the data were processed

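RNA of 22 libraries was analysed from 1 deposited table per library, which lists for each gene its Entrez gene ID, transcripts, length, an expected count, an FPKM value and a symbol. The labels name the J1 mouse ES cell line, embryoid bodies, RNA extraction with Trizol and an RNeasy Plus kit, and libraries made and sequenced at BGI. Groups, doses and replicate numbers were taken from the titles, in which the number after D was read as the day. They gave 2 untreated ES libraries and, at each of 5 days, 2 with DMSO, 1 with 10 nM and 1 with 100 nM TBBPA. The labels state no batch, sequencing date or culture of origin.

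The expected counts are the authors' estimates of mapped reads per gene, per the file headers, and 64.9 to 66.7% of them were whole numbers. Reads were aligned with HISAT and Bowtie2, and GRCm38.p5 is the genome build, per the submitters' processing notes, which give no version of either aligner. The counting tool is not given in the sources used here. The FPKM values were deposited by the authors beside the counts, per the file headers, and their lowest listed value was 0.01. A table lists only genes with a value, so a gene missing from a table was taken as 0. The tables held 19721 genes in at least 1 library and 14484 in all 22. Of these, 2 symbols were shared by 2 gene IDs, which were kept apart. Mitochondrially encoded genes (0 of 26 list members matched) were not analysed here, and strand was not stated, so overlapping genes on opposite strands are uncertain. The reference at hand is of another patch of the build, so no coordinates are given.

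Total counts were 18158583 to 18998141 per library. The 10 most abundant genes held 4.18 to 5.89% of the counts. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust dispersions and quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are CPM on the TMM library size, and the SE of a log2 change is its size divided by the square root of F.

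The control steps were tested in 1 fit of the 12 control libraries with 6 residual degrees of freedom. The TBBPA effect at each day took the 10 nM and 100 nM libraries as 2 samples against the DMSO pair, in 1 fit of 11 groups over all libraries with 11 residual degrees of freedom. That fit also tested whether the effect differed between the days. The mean of each dose over the days was fitted with the day as a factor (9 residual degrees of freedom), and both doses and their difference with 13. Each dose at a single day is 1 library, so it has no replicate of its own.

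Before the data were examined, 43 gene lists of lineages, signalling pathways and stress or metabolic responses were fixed, with 939 members, of which 898 were in the tables. The 42 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry, which asks whether a list's genes move on balance one way, stand beside it. The rule for the genes named was fixed then as well. At each day and control step it takes the 5 largest rises and 5 largest falls that passed, with a mean of at least 2 log2 CPM and both compared libraries on the same side of the controls. For a mean over days it takes 10 of each with the same sign in 4 of 5 days, and for a list that passed its 4 members of smallest p. It adds 20 fixed markers. Where fewer than 5 genes pass, it takes the 5 of smallest p.

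Alternatives fixed at that time were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors or library size alone in place of TMM, no filter or a stricter one (1 CPM in 2 libraries and 50 counts in all), and limma on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 2 libraries. Others were the libraries compared alone, each dose alone, 1 DMSO library as control, no day term, the replicate number as a block, and leaving out each library or day in turn. The settings without the ES libraries, with days 9, 12 and 18 or days 4 and 28 alone, and with each DMSO pair summed to 1 library were chosen after seeing the data. Shared DMSO libraries were allowed for by 20 simulations of unchanged groups. Labels were permuted within days in 50 splits, or in all 16 for the doses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

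The fits were tested on simulated counts with the means and library sizes of the real libraries, in which 200 genes were changed. At D12, TBBPA against DMSO recovered 77.6% of the genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold. The step from D9 to D12 recovered 65.7, 86.6 and 98.5%, and the test between days 53.7, 88.1 and 98.5%. The mean over both doses recovered 92.5, 100 and 100%, and the difference between doses 94, 97 and 100%. Genes not changed made up 3.26% of the calls at D12 and 4.43% for the difference between doses. Their share was above the threshold of 5% for the step from D9 to D12 (6.18%), 100 nM (6.83%), 10 nM (7.08%), both doses (9.3%) and the test between days (13.5%). Each simulated library was drawn independently, with 1 dispersion per gene for all groups. The simulation therefore lacks the closeness of the DMSO pairs and any shared culture, and its shares need not hold for the real calls. All intervals and p-values cover the spread between these libraries only. Results for some single genes are not reported here.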

Results

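Messenger RNA of the J1 mouse embryonic stem (ES) cell line was sequenced before and during its development as embryoid bodies, aggregates in which ES cells form derivatives of the germ layers. Embryoid bodies were kept with the vehicle, 0.1% dimethyl sulfoxide (DMSO), or with tetrabromobisphenol A (TBBPA), a brominated flame retardant, at 10 nM or 100 nM. The 22 libraries comprised 2 of untreated ES cells and, at each of days 4, 9, 12, 18 and 28 (D4 to D28, read from the titles), 2 with DMSO, 1 with 10 nM and 1 with 100 nM TBBPA. Total estimated counts lay between 18158583 and 18998141 per library, and 16427 to 17816 genes were listed. The most abundant gene was Eef1a1, a translation elongation factor, with 1.02 to 1.56% of the counts. Levels are CPM, counts scaled to the size of each library, as mean ± SD with n = 2 libraries in each group, and log2 changes are given ± SE. A gene rose or fell, or passed, when it did so at an adjusted p under 0.05 in edgeR's quasi-likelihood test.

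The libraries of the DMSO pairs differed little: the mean chi-square per gene between their counts was 1.67 to 3.61, where 1 is counting noise. It was 24.5 between the ES libraries, 3.54 to 8.46 between 10 nM and 100 nM of a day, and 5.33 to 23 between DMSO and TBBPA libraries of a day. The labels do not say that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 10 nM and 100 nM libraries of a day were tested together as a pair against the DMSO pair. Each dose mean set its 5 libraries, 1 at each day, against the 10 DMSO libraries with the day as a factor. The spread within the DMSO pairs thus enters these means too. With each DMSO pair summed to 1 library, a setting chosen after seeing the data, edgeR called 781 genes at D12, 172 at D18 and 6 at D28. It then called 0 at D4 (694 at an unadjusted p under 0.05) and 0 at D9 (918). For a difference between days it called 21, and over the days 277 for 10 nM, 130 for 100 nM and 1231 for both doses.

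The step from ES cells to D4 embryoid bodies addressed the exit from the ES state, with the vehicle entering at the same time. Fgf5, a marker of the primed epiblast (gene ID 14176), went from 0.0304 ± 0.043 to 151 ± 4.8 CPM. Acta1, skeletal alpha-actin, rose from 0.0917 ± 0.044 to 83.3 ± 6.2 CPM. Car4, a membrane carbonic anhydrase, rose 641-fold (log2 9.32 ± 0.18). Cubn, an endocytic receptor of visceral endoderm, rose from 0.336 ± 0.22 to 130 ± 10 CPM and Vrtn rose by 8.18 ± 0.21. Ly6a, the antigen Sca-1, fell from 60.7 ± 17 to 0.421 ± 0.26 CPM. Dmgdh, a mitochondrial enzyme of choline breakdown, was 132-fold lower and Mras, a Ras-family GTPase, 107-fold lower. The homeobox gene Crxos was 79.5-fold lower and the imprinted zinc-finger gene Plagl1 60.7-fold lower.

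Among pluripotency genes, 20 of 25 measured members fell, 4 rose and 1 did not pass, and 24 passed adjusted over the list alone. Tfcp2l1, a factor of the naive state, fell from 983 ± 58 to 25.5 ± 1.8 CPM and Esrrb, a nuclear receptor of the same state, from 828 ± 52 to 105 ± 1.9 CPM. Nanog fell from 1220 ± 110 to 282 ± 3.6 CPM, and Tcl1 (-3.81 ± 0.11) and Klf5 (-2.82 ± 0.08) fell as well. Pou5f1 (Oct4) fell from 1330 ± 120 to 822 ± 21 CPM. Of the endoderm genes, 17 of 20 measured members rose, 1 fell and 2 did not pass (18 adjusted over the list alone). Cldn6 was at 5.32 ± 0.08, the adaptor Dab2 at 3.88 ± 0.08 and Trh, the thyrotropin-releasing hormone precursor, at 3.25 ± 0.07. For epithelium, 13 of 20 measured members rose, 2 fell and 5 did not pass (15 adjusted over the list alone). The splicing regulator Esrp1 rose from 1.49 ± 0.72 to 139 ± 5.4 CPM, Grhl2 (3.54 ± 0.12) and Sfn (3.05 ± 0.10) rose and Elf3 fell (-2.46 ± 0.07). For smooth muscle, 10 of 12 measured members rose and 2 did not pass, among them Tagln (7.44 ± 0.09), Cnn1 (7.12 ± 0.23), Acta2 (6.41 ± 0.15) and Smtn (1.36 ± 0.06). Of the cholesterol synthesis enzymes and their regulators, 21 of 22 measured members fell and 1 rose, for example Msmo1 (-2.30 ± 0.09), Insig1 (-2.02 ± 0.08) and Fdps (-1.50 ± 0.06). These 5 lists also held with an estimated correlation.

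The other 9 lists that passed did not hold with it (adjusted p = 0.0546 to 0.647 with an estimated correlation). Of the Hox genes 25 of 31 measured members fell and 6 did not pass (adjusted p = 0.417 with an estimated correlation), with Hoxc4 at -4.34 ± 0.23. Integrated stress response genes that fell included Asns, asparagine synthetase (-2.42 ± 0.10), and Atf4 (-1.18 ± 0.05; adjusted p = 0.288 with an estimated correlation). Imprinted genes that rose included Snrpn (2.15 ± 0.05) and Mest (1.87 ± 0.07; adjusted p = 0.0546 with an estimated correlation). Adipocyte genes had a median of -0.99 and a mean of 0.13 while their test pointed down (adjusted p = 0.262 with an estimated correlation), with Lpl at -2.03 ± 0.13. Of the fixed markers, Cyp1b1, a dioxin-inducible P450, rose from 0.153 ± 0.044 to 3.43 ± 0.0033 CPM. The cardiac myosin Myh6 rose from 1.47 ± 0.27 to 8.49 ± 0.42 CPM and the thyroid hormone receptor Thra from 28.6 ± 4.1 to 67.2 ± 3.1 CPM. Pax6, Sox17, Afp, T and Cyp1a1 rose by 1.40 to 2.42, and Pecam1 (-2.73 ± 0.08), Tubb3 (-2.80 ± 0.19), Thrb (-2.76 ± 0.65), Fgf10 (-1.61 ± 0.14) and Tnnt2 (-1.26 ± 0.45) fell. Pparg, the adipocyte nuclear receptor, was listed in neither ES library and passed at 0.211 ± 0.13 CPM. By edgeR 10090 of 16203 genes passed, 5174 higher and 4916 lower at D4.

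Between D4 and D9 fibroblast matrix, yolk sac and neural progenitor genes rose in the DMSO embryoid bodies. Postn, the matrix protein periostin (gene ID 50706), rose from 0.451 ± 0.13 to 141 ± 2.7 CPM. Fbn2, a fibrillin of early microfibrils, rose from 0.782 ± 0.00075 to 133 ± 2.5 CPM. Frzb, a secreted Wnt antagonist, rose 132-fold (log2 7.05 ± 0.23). Hand1, a mesoderm and trophoblast regulator, rose 131-fold (7.03 ± 0.20) and the matrix gene Frem1 110-fold (6.79 ± 0.15). Lefty1, a Nodal antagonist, fell from 741 ± 18 to 30.3 ± 0.25 CPM. Mmp25, a membrane metalloproteinase, fell from 41.3 ± 3.6 to 1.74 ± 0.56 CPM. Tmem154 (-4.52 ± 0.23), Trim67 (-3.96 ± 0.14) and Cbr3, a carbonyl reductase (-3.85 ± 0.14), fell as well.

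Of the imprinted genes, 16 of 19 measured members rose, 2 fell and 1 did not pass (18 adjusted over the list alone). Dlk1, a Notch-family ligand, rose from 2.86 ± 0.56 to 127 ± 1.8 CPM, with Nnat (5.46 ± 0.08), Peg10 (3.08 ± 0.06) and Peg3 (3.08 ± 0.06). Of the liver and yolk sac genes, 16 of 19 measured members rose and 3 did not pass. They included the carriers Ttr (4.46 ± 0.11), Rbp4 (4.98 ± 0.12), Apom (4.20 ± 0.12) and Apoa1 (3.52 ± 0.09). Afp, alpha-fetoprotein, rose from 3.94 ± 0.63 to 293 ± 7.4 CPM. For endoderm 18 of 20 measured members rose and 2 fell, with Foxa2 (3.78 ± 0.11), Lama1 (2.82 ± 0.06) and Col4a1 (2.91 ± 0.07). For fibroblast matrix 18 of 22 measured members rose, 1 fell and 3 did not pass. Col1a1 rose from 5.93 ± 0.048 to 184 ± 5.4 CPM, with Col1a2 (4.98 ± 0.13) and Fn1 (1.82 ± 0.05). BMP and TGF-beta genes rose in 21 of 25 cases, such as Bmp2 (4.51 ± 0.14), Fst (4.65 ± 0.13) and Id2 (2.98 ± 0.13). Wnt genes rose in 24 of 30 and fell in 3, such as Dkk1 (4.90 ± 0.15) and Wnt5a (4.57 ± 0.14). Wnt1 was listed in neither D4 library and stood at 33.9 ± 0.054 CPM at D9. In Notch and hedgehog signalling 18 of 25 rose. The ligand Shh rose from 0.0301 ± 0.043 to 31.8 ± 2 CPM, with Gli1 (3.29 ± 0.12) and Ptch1 (1.37 ± 0.06).

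Of 22 neural progenitor genes 16 rose, among them Sox1 (4.28 ± 0.13) and Pou3f2 (5.53 ± 0.18). Zic2 (-2.40 ± 0.07) and Pou3f1 (-2.69 ± 0.10) were among the 5 that fell. Axon guidance genes rose in 20 of 32 cases and fell in 5, for example Slit2 (5.56 ± 0.11). Neural crest genes rose in 12 of 15 and fell in 2, for example Pax3 (5.66 ± 0.30) and Twist1 (3.19 ± 0.13). Endothelial genes (12 of 20) were led by Cdh5 (7.46 ± 0.24) and Sox17 (3.92 ± 0.15). The streak and mesoderm genes (14 of 20) were led by Kdr (6.95 ± 0.25) and T, brachyury (4.32 ± 0.20), while Fgf5 fell (-3.08 ± 0.09). Trophoblast, FGF and retinoic acid, lipid transport and estrogen-responsive lists also pointed up, with Krt7 (2.70 ± 0.10), Crabp1 (4.57 ± 0.15), Apoc2 (4.56 ± 0.17) and Greb1 (3.65 ± 0.09) as examples. These 16 lists held with an estimated correlation.

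The other 10 lists did not hold with it (adjusted p = 0.0542 to 0.54 with an estimated correlation). Pluripotency genes fell in 15 of 25 cases and rose in 5 (adjusted p = 0.117 with an estimated correlation). Pou5f1 fell from 822 ± 21 to 239 ± 7.4 CPM and Tdgf1 by 2.28 ± 0.07, while Tfcp2l1 rose (1.62 ± 0.08). All 26 ribosomal protein genes fell (adjusted p = 0.302 with an estimated correlation), for example Rpl4 (-0.70 ± 0.07). So did 17 of 25 cell cycle genes (adjusted p = 0.074 with an estimated correlation), for example Mcm2 (-0.82 ± 0.05). Neuron genes rose in 16 of 26 cases and fell in 3 (adjusted p = 0.316 with an estimated correlation), with Tubb3 at 3.20 ± 0.19 and Dcx at 5.13 ± 0.32. Further fixed markers that rose were Pparg, Thrb, Tnnt2, Cyp1b1, Fgf10, Pax6, Myh6 and Hbb-bh1, an embryonic globin now at 2.74 ± 0.39 CPM. Thra (-0.67 ± 0.08), Nanog (-0.87 ± 0.06) and Cyp1a1 (-1.60 ± 0.47) fell. Altogether 9849 of 16203 genes passed, 5170 higher and 4679 lower at D9. With library size alone as the scaling the split was 6311 higher and 3458 lower.

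From D9 to D12 Corin, a membrane protease (gene ID 53419), rose from 1.29 ± 0.6 to 16.4 ± 1.4 CPM and Neurog2, a proneural factor, from 3.33 ± 0.066 to 35.6 ± 0.39 CPM. Fabp7, a fatty acid binding protein of radial glia, rose 10.7-fold (log2 3.41 ± 0.16) and the embryonic globin Hbb-bh1 9.33-fold (3.22 ± 0.20). Fgf5 fell from 17.9 ± 0.9 to 2.91 ± 0.23 CPM, as did Irs4, an insulin receptor substrate (-2.31 ± 0.15), Vrtn (-2.24 ± 0.15), the hormone precursor Trh (-1.84 ± 0.07) and the transcription factor Tfec (-1.81 ± 0.17).

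For neurons 24 of 26 measured members rose and 2 did not pass (25 adjusted over the list alone). Doublecortin, Dcx, rose from 4.46 ± 0.59 to 35.2 ± 3.1 CPM, with the vesicular glutamate transporter Slc17a6 (3.98 ± 0.24), Map2 (2.15 ± 0.08), Elavl3 (1.96 ± 0.11) and Tubb3 (1.32 ± 0.13). Neural progenitor genes rose in 13 of 22 cases and fell in 5, among them Zic1 (1.73 ± 0.09). Axon guidance genes rose in 19 of 32 and fell in 4, among them Dcc (2.62 ± 0.18). Of the fibroblast matrix genes 20 of 22 measured members rose, 1 fell and 1 did not pass. Col1a1 rose from 184 ± 5.4 to 749 ± 42 CPM, Lum by 3.16 ± 0.12 and Dcn by 1.93 ± 0.11. Cardiac genes rose in 18 of 24 cases, including the atrial light chain Myl7 (2.91 ± 0.19), Myh6 (1.69 ± 0.09) and Tnnt2 (1.92 ± 0.20). Erythroid genes rose in 7 of 14. Hba-x rose from 2.23 ± 0.34 to 18.2 ± 0.71 CPM and Hba-a1 by 3.19 ± 0.29, where reads of near-identical globin copies make single genes uncertain. Smooth muscle, endothelium, p53 target and immediate early gene lists pointed up, with Actg2 (2.66 ± 0.15), Tie1 (1.37 ± 0.20), Cdkn1a (0.94 ± 0.06) and Egr1 (1.65 ± 0.07). Cell cycle genes fell in 20 of 25 cases, for example Pcna (-0.53 ± 0.05). Streak genes fell in 9 of 20 and rose in 3, for example T (-1.47 ± 0.15). These 12 lists held with an estimated correlation.

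The other 10 lists that passed did not hold with it (adjusted p = 0.0777 to 0.51 with an estimated correlation). Glial genes rose in 6 of 16 cases and fell in 1 (adjusted p = 0.22 with an estimated correlation), with Olig2 at 2.74 ± 0.22. Notch and hedgehog genes rose in 11 of 25 and fell in 5 (adjusted p = 0.0902 with an estimated correlation), with Hes5 at 1.53 ± 0.15. The neural crest test pointed up with a mean of 0.24 and a median of -0.16 (adjusted p = 0.107 with an estimated correlation), with Ednrb at 2.43 ± 0.12. Pluripotency genes fell in 10 of 25 cases and rose in 1 (adjusted p = 0.404 with an estimated correlation), with Sall4 at -0.66 ± 0.08. Among the fixed markers Pax6 (0.86 ± 0.13), Thra (0.75 ± 0.08), Cyp1b1 (0.63 ± 0.08), Afp (0.31 ± 0.10) and Pecam1 (0.25 ± 0.08) rose. Fgf10 (-0.48 ± 0.12) and Pou5f1 (-0.34 ± 0.07) fell. The count was 5361 of 16203 genes, 2828 higher and 2533 lower at D12, or 3409 and 1786 with library size alone as the scaling. The count was 3236 to 3426 when any 1 of the 4 libraries compared was left out, and 8056 with these 4 libraries alone in the fit.

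Between D12 and D18 epithelial, fibroblast matrix and skeletal muscle genes rose. Krt5, a keratin of basal epithelium (gene ID 110308), rose from 1.15 ± 0.18 to 48 ± 0.23 CPM, and its partner Krt14 by 4.30 ± 0.18. Lox, a collagen crosslinking oxidase, rose from 7.32 ± 0.42 to 187 ± 1 CPM, Eln, elastin, from 3.65 ± 0.46 to 76.3 ± 4.9 CPM and Myh3, embryonic skeletal myosin, from 1.12 ± 0.15 to 24 ± 2.8 CPM. Car7, a carbonic anhydrase, fell from 14.3 ± 0.75 to 1.35 ± 0.081 CPM, as did the apolipoproteins Apom (-2.91 ± 0.11) and Apoc2 (-2.82 ± 0.16), Slc13a4 (-2.75 ± 0.08) and Igdcc3 (-2.56 ± 0.07).

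For fibroblast matrix 19 of 22 measured members rose, 2 fell and 1 did not pass (21 adjusted over the list alone). Dcn rose from 9.77 ± 0.14 to 87.9 ± 0.58 CPM, with Col6a1 (2.42 ± 0.08) and Col1a1 (1.35 ± 0.07). For skeletal muscle 12 of 15 measured members rose, 1 fell and 2 did not pass. Myog, the myogenic factor, rose by 4.82 ± 0.33, Myl1 by 4.84 ± 0.26 and Myh8 by 4.35 ± 0.33. Neuron genes rose in 21 of 26 cases and fell in 2, among them Mapt (2.41 ± 0.08), Scg2 (2.74 ± 0.13) and Dcx (1.80 ± 0.08). Axon and synapse genes rose in 25 of 32 and fell in 4. Glial genes rose in 9 of 16, with Gfap, the astrocyte filament, from 0.0765 ± 0.036 to 9.89 ± 0.87 CPM and Ptprz1 at 2.43 ± 0.08. Epithelial genes rose in 10 of 20 and fell in 4, with Krt15 at 4.21 ± 0.13. Liver and yolk sac genes fell in 14 of 19 cases and rose in 1, for example Apob (-2.27 ± 0.08), Rbp4 (-2.01 ± 0.09) and Ttr (-1.67 ± 0.08). The lipid transport list, which shares Apob, pointed down too. Erythroid genes fell in 9 of 14 and rose in 1, and Hbb-bh1 fell from 25.4 ± 1.5 to 0.149 ± 0.14 CPM. Cell cycle genes fell in 24 of 25, for example Cdc20 (-0.82 ± 0.05). These 10 lists held with an estimated correlation.

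The other 6 did not hold with it (adjusted p = 0.0525 to 0.611 with an estimated correlation). Pluripotency, ribosomal protein, endothelial and NRF2 genes pointed down, with Esrrb (-0.50 ± 0.07), Rps2 (-0.35 ± 0.06), Tie1 (-2.27 ± 0.22) and Srxn1 (-0.90 ± 0.10). Inflammation and leukocyte genes pointed up, with the complement gene C3 (2.62 ± 0.35) and Lyz2 (3.33 ± 0.37). Of the fixed markers Cyp1b1 (1.48 ± 0.07), Thra (1.30 ± 0.07), Sox17 (0.99 ± 0.09), Tubb3 (0.90 ± 0.13), Pax6 (0.88 ± 0.11), Myh6 (0.50 ± 0.08) and Tnnt2 (0.50 ± 0.16) rose. T (-1.32 ± 0.18), Fgf10 (-0.81 ± 0.13), Afp (-0.77 ± 0.10), Pecam1 (-0.55 ± 0.08), Pou5f1 (-0.46 ± 0.07) and Nanog (-0.32 ± 0.06) fell. A total of 6110 of 16203 genes passed, 3347 higher and 2763 lower at D18.

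From D18 to D28 neuronal genes fell while glial, epithelial and fibroblast matrix genes rose. Gfap (gene ID 14580) rose from 9.89 ± 0.87 to 696 ± 4.4 CPM, 70.1-fold (log2 6.13 ± 0.11). Krt13 and Krt4, keratins of mucosal epithelium, rose from 0.174 ± 0.034 to 61.1 ± 0.54 CPM and from 2.29 ± 0.088 to 164 ± 13 CPM. Lor, the cornified envelope protein loricrin, rose from 1.02 ± 0.027 to 68.9 ± 10 CPM and Ltf, lactoferrin, by 7.05 ± 0.28. Nhlh2 and Nhlh1, factors of young neurons, fell (-4.77 ± 0.18 and -4.46 ± 0.19). The neuronal zinc-finger genes Scrt2 (-4.70 ± 0.27) and Scrt1 (-4.07 ± 0.21) fell, as did the axonal adhesion gene Cntn2, from 75.5 ± 1.3 to 4.75 ± 0.072 CPM.

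For neurons 25 of 26 measured members fell and 1 did not pass (26 adjusted over the list alone). Dcx fell from 122 ± 0.57 to 8.39 ± 0.57 CPM and Tubb3 from 222 ± 8.5 to 25.1 ± 1.5 CPM, with Elavl3 (-3.06 ± 0.11) and Map2 (-1.87 ± 0.07). Neural progenitor genes fell in 21 of 22 cases, for example Hes5 (-3.21 ± 0.19) and Neurog2 (-2.84 ± 0.12). Axon guidance genes fell in 18 of 32 and rose in 7, for example Dcc (-3.59 ± 0.17), and Notch and hedgehog genes in 14 of 25 and rose in 3, for example Shh (-2.47 ± 0.14). Glial genes rose in 9 of 16 and fell in 1, with the water channel Aqp4 from 1.79 ± 0.014 to 68.9 ± 2.7 CPM. Fibroblast matrix genes rose in 21 of 22, with Col1a1 from 1890 ± 96 to 5810 ± 180 CPM. Epithelial genes rose in 16 of 20, with Krt15 (3.54 ± 0.08) and Krt14 (2.12 ± 0.11). Leukocyte genes rose in 15 of 18, including lysozyme, Lyz2 (3.77 ± 0.17), and inflammation genes in 18 of 21, including Lcn2 (6.24 ± 0.35). Skeletal muscle genes rose in 12 of 15, including Myh8 (2.41 ± 0.18), and xenobiotic metabolism genes in 12 of 18 and fell in 1, including Ephx1 (2.08 ± 0.08) and Cyp1b1 (0.95 ± 0.07). Estrogen-responsive genes pointed up with Ltf and Wnt4 (1.74 ± 0.10). Cell cycle genes fell in 24 of 25 cases, for example Mki67 (-1.55 ± 0.06). Cholesterol synthesis genes fell in 20 of 22 and imprinted genes in 12 of 19 and rose in 2, for example Nnat (-2.71 ± 0.07). These 15 lists held with an estimated correlation.

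The other 3 did not hold with it. Pluripotency genes fell in 19 of 25 cases and rose in 2 (adjusted p = 0.217 with an estimated correlation). Adipocyte genes rose in 12 of 17 and fell in 1 (adjusted p = 0.0664 with an estimated correlation), for example Cebpa (1.92 ± 0.12), and BMP and TGF-beta genes rose in 14 of 25 and fell in 1 (adjusted p = 0.0934 with an estimated correlation). Pou5f1 and Nanog fell and still stood at 85.5 ± 4 and 81.4 ± 1.9 CPM at D28. The fixed markers Thrb (1.21 ± 0.25) and Sox17 (0.43 ± 0.09) rose, and Afp (-1.50 ± 0.10), T (-1.63 ± 0.24), Pax6 (-0.98 ± 0.11), Pecam1 (-0.59 ± 0.09) and Pparg (-0.64 ± 0.22) fell. Hbb-bh1, which passed, was listed in neither D28 library after 0.149 ± 0.14 CPM at D18. The number passing was 8589 of 16203, 4031 higher and 4558 lower at D28.

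**Figure D1:**
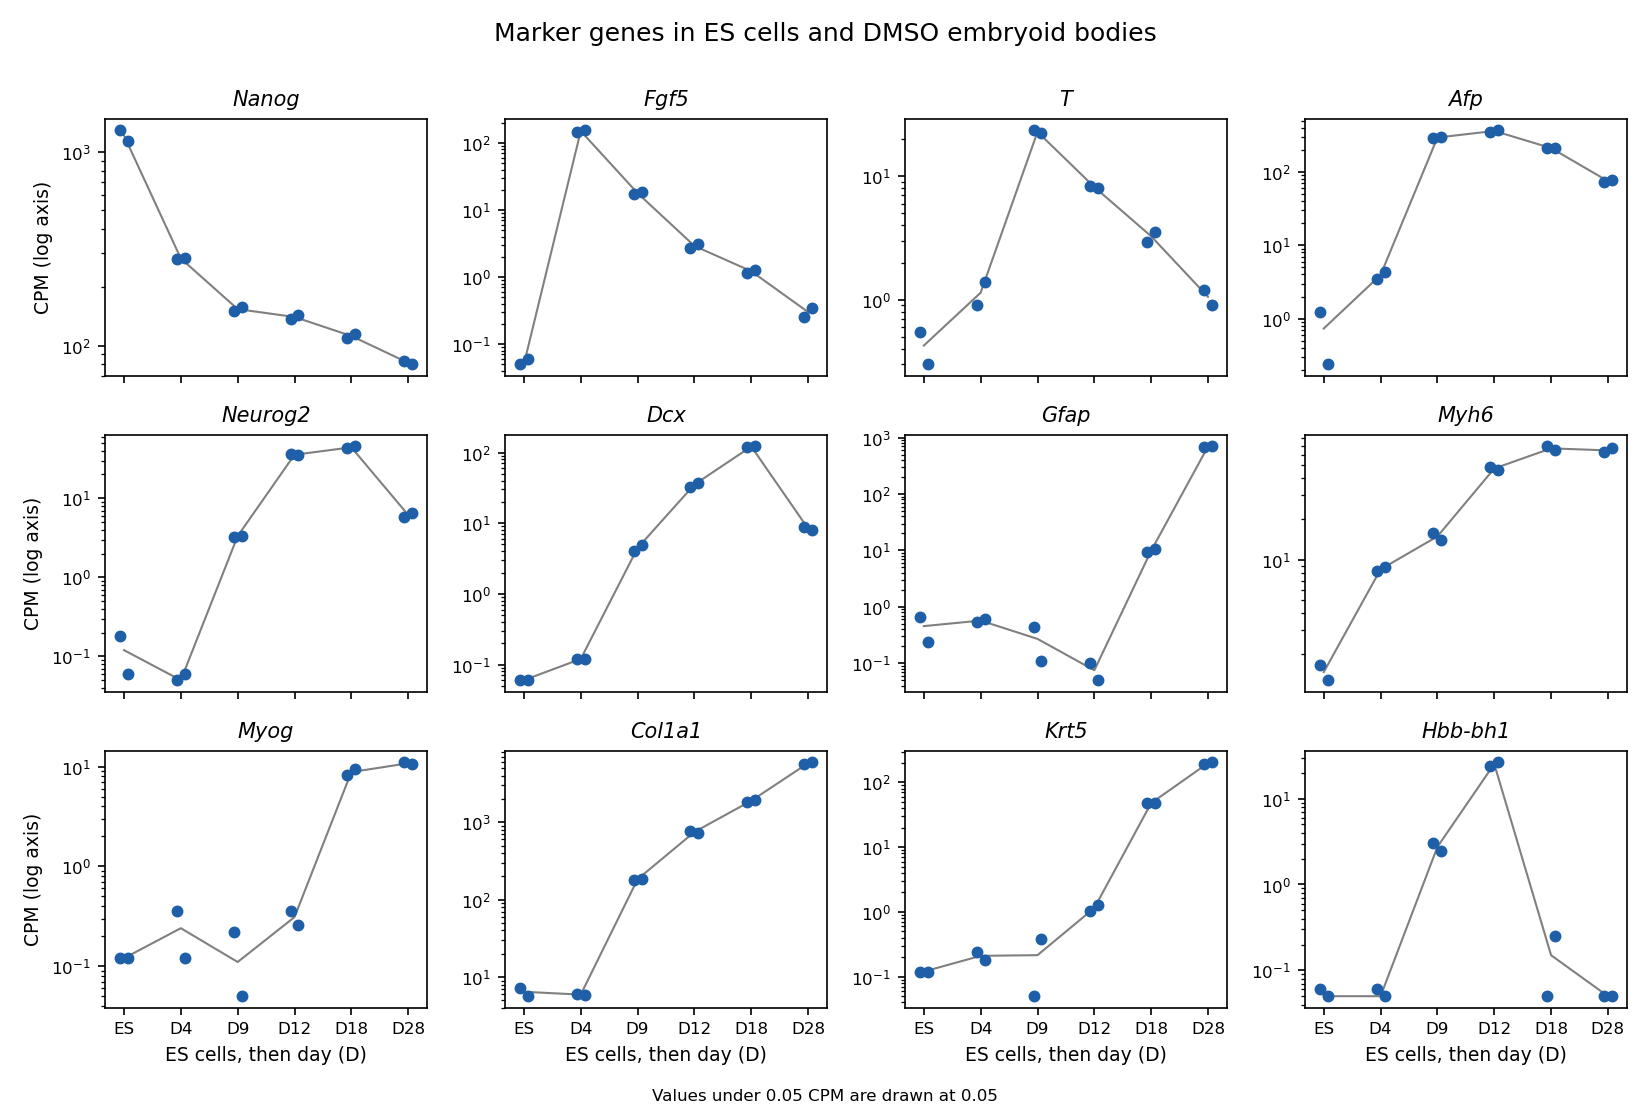
Levels of 12 marker genes (CPM, log axis) in the control libraries against sampling time (ES cells, then days 4 to 28); points are single libraries and lines join the means of n = 2, with values under 0.05 CPM drawn at 0.05. Nanog is highest in ES cells, Dcx peaks at day 18 and Gfap reaches 696 CPM at day 28.

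The comparisons at each day asked how embryoid bodies given TBBPA differed from those given the vehicle. At D4 few genes passed, and most of these were lower with TBBPA. Dppa3, a gene of germ cells and naive ES cells (gene ID 73708), fell from 18.3 ± 0.49 to 7.62 ± 2.8 CPM, and the germ cell kinase gene Stk31 from 9.93 ± 0.59 to 5.22 ± 0.34 CPM. Arl14epl (-1.44 ± 0.26), AU018091 (-0.86 ± 0.14) and Ism2 (-0.85 ± 0.19) fell as well. Pim2, a growth-promoting kinase gene, rose from 199 ± 6.7 to 319 ± 23 CPM and the circadian repressor Bhlhe41 from 14.3 ± 1.4 to 28.6 ± 9.9 CPM. Vat1l rose by 0.78 ± 0.15, the homeobox gene Meis3 by 0.71 ± 0.16 and Ube2e2 by 0.59 ± 0.13. The endothelial adhesion gene Pecam1, also expressed by ES cells, fell from 28.7 ± 0.027 to 17.4 ± 2.3 CPM, and none of the other 19 fixed markers passed.

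Pluripotency genes fell in 6 of 25 cases (13 adjusted over the list alone), among them Tfcp2l1 (-0.58 ± 0.11), Tdh, threonine dehydrogenase (-0.59 ± 0.12), and Sox2 (-0.39 ± 0.08). The list was lost with an estimated correlation (adjusted p = 0.263). The germ cell list pointed down with 1 of 12 members passing, Dppa3, and 8 adjusted over the list alone, and it held (adjusted p = 0.0446 with an estimated correlation). Its members Prdm14 (-1.08 ± 0.24) and Mael (-0.74 ± 0.18) did not pass. The other 5 lists that passed, of 1 passing member at most each, did not hold with it (adjusted p = 0.424 to 0.762 with an estimated correlation), with Rps23 (-0.29 ± 0.07), the lactate dehydrogenase Ldha (0.43 ± 0.07) and the cell cycle inhibitor Cdkn1a (-0.31 ± 0.06). In edgeR's test 75 of 16383 genes passed at D4, 14 higher and 61 lower with TBBPA. The count was 5 without the DMSO 1 library, 5 without DMSO 2, 29 without 10 nM and 1 without 100 nM TBBPA, and of the genes named here as passing only Pim2 kept its call in each of these fits.

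At D9 genes of neural progenitors were higher with TBBPA and genes of epithelium and trophoblast lower. Zic1, a zinc-finger gene of the neural plate (gene ID 22771), rose from 14 ± 1.2 to 38.6 ± 10 CPM and Dcc, a netrin receptor of growing axons, from 3.01 ± 0.16 to 8.01 ± 0.091 CPM. Rspo1, a Wnt agonist, rose from 4.11 ± 0.18 to 10.9 ± 2 CPM, Pax7, of the dorsal neural tube, from 3.81 ± 0.087 to 9.33 ± 4 CPM and Wnt8b, of the forebrain, from 3.95 ± 0.56 to 9.05 ± 1.3 CPM. Vgll2, a cofactor of muscle genes, fell from 9.45 ± 0.35 to 2.99 ± 2 CPM, the homeobox gene Tlx1 by 1.28 ± 0.30 and the adrenergic receptor gene Adra2b by 1.28 ± 0.31. Rhox9 (-1.22 ± 0.29) and Rhox6 (-1.22 ± 0.29) fell too, and reads of this X-linked homeobox cluster may be shared between copies. Of the fixed markers Pax6 (0.85 ± 0.14) and Tubb3 (0.61 ± 0.12) rose and the cardiac myosin Myh6 fell (-0.90 ± 0.19). Of these genes Pax7, Wnt8b, Vgll2, Tlx1, Adra2b, Rhox9, Rhox6, Tubb3 and Myh6 lost their call when 1 library was left out.

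Neural progenitor genes rose in 8 of 22 cases (18 in either direction adjusted over the list alone). They included Sox1, from 34 ± 0.62 to 57.5 ± 11 CPM. For epithelium 8 of 20 measured members fell and 12 did not pass, including Krt7 (-0.86 ± 0.11), Grhl2 (-0.69 ± 0.13) and Sfn (-0.66 ± 0.14). Trophoblast genes fell in 3 of 13 cases, including Eomes (-0.78 ± 0.12) and Tfap2c (-0.54 ± 0.11). These 3 of 18 lists that passed held with an estimated correlation. Among the other 15 (adjusted p = 0.0522 to 0.474 with an estimated correlation), neuron genes rose in 4 of 26 cases (adjusted p = 0.0522 with an estimated correlation), with Elavl3 at 0.67 ± 0.12. Notch and hedgehog genes rose in 4 of 25 (adjusted p = 0.0522 with an estimated correlation), with the ligand Dll1 at 0.75 ± 0.13. The median log2 difference of this list from DMSO was 0.284 in the 10 nM library and -0.008 in the 100 nM library. Wnt genes rose in 6 of 30 and fell in 1 (adjusted p = 0.0916 with an estimated correlation), with Wnt1 at 0.89 ± 0.11. Cardiac genes fell in 4 of 24 cases (adjusted p = 0.0959 with an estimated correlation), with Hand2 at -1.03 ± 0.22. Endoderm genes fell in 2 of 20 (adjusted p = 0.204 with an estimated correlation), with Hnf4a at -0.61 ± 0.14. Leaving out 1 library ended the calls of Grhl2, Sfn, Tfap2c, Elavl3, Dll1, Hand2 and Hnf4a.

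In edgeR's test 383 of 16383 genes passed at D9, 225 higher and 158 lower with TBBPA. The count was 93 without either DMSO library and 183 without the 100 nM library.

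At D12 TBBPA went with higher levels of genes of neural progenitors and neurons. Hes5, a Notch target of neural progenitors (gene ID 15208), rose 2.88-fold, from 15.6 ± 0.2 to 45 ± 3.3 CPM. Stmn4, a tubulin-binding protein of neurons, rose from 12.4 ± 0.43 to 32.8 ± 0.98 CPM and Cartpt, a neuropeptide precursor, from 4.03 ± 0.78 to 11.4 ± 0.57 CPM. Syt4, a synaptotagmin, rose by 1.36 ± 0.20 and Btbd17 by 1.39 ± 0.14. Ctsj, a cathepsin of the placenta with close copies, fell 3.79-fold, from 22.3 ± 1.1 to 5.87 ± 0.72 CPM. Gpr50, a melatonin receptor relative, fell from 7.73 ± 0.59 to 2.11 ± 0.033 CPM and the adhesion receptor Adgrf5 from 23.3 ± 0.65 to 8.11 ± 0.94 CPM. Tdo2, a tryptophan-degrading enzyme of the liver, fell by 1.53 ± 0.29 and Plet1, a trophoblast and epithelial surface protein, by 1.45 ± 0.19.

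For neurons 21 of 26 measured members rose and 5 did not pass (24 adjusted over the list alone). Tubb3, neuronal tubulin, rose from 119 ± 4 to 258 ± 3.9 CPM, with Stmn3 (1.35 ± 0.12), Celf3 (1.33 ± 0.12) and Map2 (0.87 ± 0.08). For neural progenitors 17 of 22 measured members rose, 1 fell and 4 did not pass (20 adjusted over the list alone). The fatty acid binding protein gene Fabp7 rose from 47.6 ± 0.7 to 107 ± 0.76 CPM and Neurog2 (1.07 ± 0.10). These 2 of 24 lists that passed held with an estimated correlation. Among the other 22 (adjusted p = 0.0519 to 0.423 with an estimated correlation), pluripotency genes fell in 18 of 25 cases and rose in 1 (adjusted p = 0.118 with an estimated correlation), with Nanog from 141 ± 4.3 to 87.5 ± 4 CPM and Fgf4 (-1.01 ± 0.12). Epithelial genes fell in 15 of 20 (adjusted p = 0.0519 with an estimated correlation), with Cdh1, E-cadherin, from 344 ± 7.7 to 214 ± 3.8 CPM. Endoderm genes fell in 14 of 20 and rose in 2 (adjusted p = 0.113 with an estimated correlation), with Cubn from 145 ± 1.6 to 72.1 ± 5.6 CPM and Dab2 (-0.82 ± 0.07), while Cxcr4 rose (0.92 ± 0.12). Liver and yolk sac genes fell in 12 of 20 cases and rose in 1 (adjusted p = 0.16 with an estimated correlation), with Fgb at -1.16 ± 0.20. Fibroblast matrix genes fell in 8 of 22 (adjusted p = 0.258 with an estimated correlation), with Fn1, fibronectin, at -0.65 ± 0.07. Leukocyte genes fell in 3 of 18 (adjusted p = 0.352 with an estimated correlation), with Csf1r at -1.06 ± 0.17. NRF2 targets fell in 7 of 21 cases and rose in 1 (adjusted p = 0.16 with an estimated correlation), with heme oxygenase, Hmox1, at -0.53 ± 0.10.

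Among fixed markers Pax6 (0.82 ± 0.13), T (0.77 ± 0.16) and Thra (0.24 ± 0.08) rose, and Pparg (-1.08 ± 0.24), Pecam1 (-0.80 ± 0.10), Pou5f1 (-0.56 ± 0.13), Col1a1 (-0.51 ± 0.17) and Fgf10 (-0.49 ± 0.14) fell. The calls of Nanog, Thra, Pou5f1, Col1a1 and Fgf10 were lost when 1 library was left out. At D12 3452 of 16383 genes passed, 1947 higher and 1505 lower with TBBPA. The count was 1847 and 1718 without DMSO 1 and DMSO 2, 2170 without the 10 nM library and 1757 without the 100 nM library.

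At D18 neuronal genes were again higher with TBBPA, and skeletal muscle, cardiac and fibroblast matrix genes were lower. Lhx9, a homeobox gene of the forebrain (gene ID 16876), rose from 7.31 ± 0.8 to 21.1 ± 6.3 CPM. Tal2 (1.47 ± 0.17), Tal1 (1.32 ± 0.19) and Sox14 (1.29 ± 0.27), factors of inhibitory neurons of the midbrain, rose too, as did the ion channel gene Asic4, from 14.7 ± 1.3 to 37.9 ± 4 CPM. Myh3, embryonic skeletal myosin, fell 5.56-fold, from 24 ± 2.8 to 4.31 ± 1.2 CPM. Myh8, perinatal myosin, fell from 8.42 ± 0.64 to 2.23 ± 0.17 CPM and Atp2a1, the calcium pump of fast muscle, from 10.2 ± 0.68 to 2.58 ± 1.2 CPM. The lens crystallin gene Cryaa fell from 14.1 ± 0.31 to 3.43 ± 1.5 CPM, and Ctsj by 1.91 ± 0.15.

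For neurons 20 of 26 measured members rose and 6 did not pass (23 adjusted over the list alone). Tubb3 rose from 222 ± 8.5 to 391 ± 44 CPM, with Stmn3 (0.95 ± 0.11) and Elavl3 (0.75 ± 0.08). Neural progenitor genes rose in 15 of 22 cases and fell in 1, with Sox1 at 0.94 ± 0.11. Glial genes rose in 6 of 16, with the glutamate transporter Slc1a2 at 0.61 ± 0.12. For skeletal muscle 13 of 15 measured members fell and 2 did not pass (13 adjusted over the list alone), with Myog (-2.47 ± 0.34) and Acta1, from 19.2 ± 0.29 to 8.6 ± 0.78 CPM. For fibroblast matrix 19 of 22 measured members fell and 3 did not pass, with Col1a1 from 1890 ± 96 to 1110 ± 340 CPM and Ogn (-1.47 ± 0.15). Cardiac genes fell in 9 of 24 cases, with Actc1 from 56.4 ± 4.7 to 19.5 ± 5.2 CPM and Actn2 (-1.41 ± 0.14), and smooth muscle genes in 4 of 12, with Mylk at -1.03 ± 0.12. Epithelial genes fell in 11 of 20, with Grhl2 at -0.88 ± 0.13, and trophoblast genes in 4 of 13, with Krt7 at -0.75 ± 0.11. These 9 of 17 lists that passed held with an estimated correlation. Among the other 8 (adjusted p = 0.0862 to 0.509 with an estimated correlation), FGF and retinoic acid genes fell in 6 of 29 cases and rose in 1 (adjusted p = 0.184 with an estimated correlation), with the receptor gene Rarb at -0.92 ± 0.19, while Fgf15 rose (0.95 ± 0.08). Endoderm genes rose in 2 of 20 (adjusted p = 0.509 with an estimated correlation), with Sox17 at 0.49 ± 0.08.

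Fixed markers T (0.68 ± 0.20) and Thra (0.35 ± 0.08) rose, and Tnnt2 (-1.11 ± 0.19), Pparg (-1.09 ± 0.25), Myh6 (-0.85 ± 0.14) and Cyp1b1 (-0.45 ± 0.10) fell. Without 1 library the calls of Sox14, Atp2a1, Slc1a2, Col1a1, Rarb, T, Thra, Pparg and Cyp1b1 were lost. At D18 1723 of 16383 genes passed, 976 higher and 747 lower with TBBPA. The count was 735 and 786 without DMSO 1 and DMSO 2 and 900 without the 100 nM library.

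At D28 skeletal muscle genes were lower with TBBPA and genes of cell division higher. Pga5, a stomach pepsinogen (gene ID 58803), rose 2.17-fold, from 62.5 ± 0.77 to 135 ± 2 CPM. S100g, an intestinal calcium-binding protein, rose from 22.2 ± 1.3 to 47.4 ± 17 CPM, Isx, an intestine homeobox gene, from 4.62 ± 0.25 to 9.84 ± 0.095 CPM, the nucleoside transporter gene Slc28a2 from 2.94 ± 0.13 to 7.6 ± 1.2 CPM and Nepn by 1.07 ± 0.20. Cym, the milk-clotting protease chymosin, fell from 9.45 ± 0.42 to 2.24 ± 0.22 CPM and Bpifa1, an airway secretory protein, from 9.93 ± 0.89 to 2.73 ± 1.9 CPM. The muscle genes Myl1 (-1.66 ± 0.37), Ankrd2 (-1.65 ± 0.33) and Atp2a1 (-1.59 ± 0.35) fell. Among these S100g, Isx, Nepn, Bpifa1, Myl1, Ankrd2 and Atp2a1 lost their call when 1 library was left out.

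For skeletal muscle 14 of 15 measured members fell and 1 did not pass (14 adjusted over the list alone), with Acta1 from 70.5 ± 4.2 to 37 ± 12 CPM and Tnnt3 (-1.15 ± 0.18). For S phase and mitosis 16 of 25 measured members rose and 9 did not pass (22 adjusted over the list alone), with Birc5 (0.48 ± 0.08), Plk1 (0.38 ± 0.07) and Ccnb1 (0.29 ± 0.06). These 2 of 20 lists that passed held with an estimated correlation. Among the other 18 (adjusted p = 0.0738 to 0.43 with an estimated correlation), endoderm genes rose in 12 of 20 cases (adjusted p = 0.0738 with an estimated correlation), with Sox17 from 87 ± 2.7 to 134 ± 1.9 CPM, Gata4 (0.64 ± 0.11) and Foxa2 (0.57 ± 0.10). Neuron genes rose in 6 of 26 (adjusted p = 0.0965 with an estimated correlation), with the neurofilament gene Nefl at 0.77 ± 0.14. Fibroblast matrix genes fell in 11 of 22 cases and rose in 1 (adjusted p = 0.19 with an estimated correlation), with Col1a1 from 5810 ± 180 to 3780 ± 320 CPM, and cardiac genes in 5 of 24 and rose in 1 (adjusted p = 0.14 with an estimated correlation), with Actc1 at -1.28 ± 0.18. Axon guidance genes fell in 5 of 32 (adjusted p = 0.19 with an estimated correlation), with Nrp2 at -0.60 ± 0.10. Xenobiotic metabolism genes fell in 4 of 18 (adjusted p = 0.0965 with an estimated correlation), with Ahr, the dioxin receptor, at -0.86 ± 0.17 and its target Cyp1b1 at -0.42 ± 0.10. The Wnt list pointed down (adjusted p = 0.269 with an estimated correlation), with Fzd1 at -0.60 ± 0.08. The calls of Col1a1, Ahr and Cyp1b1 did not survive the loss of 1 library.

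In edgeR's test 1162 of 16383 genes passed at D28, 598 higher and 564 lower with TBBPA, or 432 and 688 with library size alone as the scaling. The count fell sharply without either DMSO library or the 100 nM library and rose without the 10 nM library. The calls at D28 thus rest more on the 100 nM than on the 10 nM library, and so did those of the other days. At D28 these 2 libraries differed by a mean chi-square of 8.46 per gene, the largest between the doses at any day.

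The effect of TBBPA was tested for a difference between the days. Pga5, the pepsinogen, was at -1.02 ± 0.12 at D12 and 1.12 ± 0.08 at D28 (edgeR's adjusted p = 1.88e-08 for the difference between days). Among endoderm genes Dab2 was at -0.82 ± 0.07 and 0.36 ± 0.07 (edgeR's adjusted p = 1.8e-06), Cubn at -1.01 ± 0.13 and 0.28 ± 0.15 (adjusted p = 0.000695) and Gata4 at -0.65 ± 0.12 and 0.64 ± 0.11 (adjusted p = 0.000246). The neuronal gene Tubb3 was at -0.14 ± 0.24 at D4, 0.61 ± 0.12 at D9, 1.11 ± 0.11 at D12, 0.81 ± 0.11 at D18 and 0.36 ± 0.14 at D28 (edgeR's adjusted p = 0.0122). Neurog2 was at 1.07 ± 0.10 at D12 and -0.51 ± 0.16 at D28 (edgeR's adjusted p = 0.000123). In a test of lists between D28 and D12, chosen after the results were seen, the endoderm list had a median of -0.55 at D12 and 0.44 at D28 (adjusted p = 0.0233 for the difference with an estimated correlation). The neuron list had medians of 0.997 and 0.31 (adjusted p = 0.0276 for the difference with an estimated correlation). Across genes, which are not independent replicates, the effects correlated with r = 0.258 between D12 and D18, which have no library in common, and with r = 0.048 between D12 and D28. At D12 and D18 together 665 genes were higher, where independent lists would share 116, and 289 lower, where they would share 68.6. In all 1708 of 16383 genes passed for a difference between the days, and 21 with each DMSO pair summed. The count was 3343 and 3356 without ES 1 and ES 2. The count was 1138 and 1080 without DMSO 1 and DMSO 2 of D12, 1136 without 100 nM of D12, and 1074 and 1015 without DMSO 1 and DMSO 2 of D28.

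Averaged over the days, 10 nM TBBPA (n = 5 libraries, 1 at each day) was compared with DMSO (n = 10 libraries). Part of the 9 residual degrees of freedom comes from within the DMSO pairs, whose spread may be technical. Stmn3, a tubulin-binding protein of neurons (gene ID 20262), rose 1.88-fold (log2 0.91 ± 0.10). It was followed by Syt4 (0.89 ± 0.12), Foxb1 (0.88 ± 0.09), Dbx1 (0.84 ± 0.10), Celf3 (0.83 ± 0.12), Stmn4 (0.82 ± 0.11), Dpysl4 (0.81 ± 0.10), Atcay (0.79 ± 0.10), Gprin1 (0.79 ± 0.10) and Tubb3 (0.77 ± 0.09). Adgrf5 fell 2.34-fold (log2 -1.23 ± 0.08) and Rhox9 by 1.20 ± 0.09. Next came Zfp36l3 (-0.97 ± 0.18), the galectin Lgals3 (-0.95 ± 0.10), Arhgef6 (-0.92 ± 0.16), Ttn, the muscle protein titin (-0.88 ± 0.19), Pakap (-0.82 ± 0.12), Fstl3 (-0.81 ± 0.10), Rec114 (-0.74 ± 0.11) and AU018091 (-0.74 ± 0.06). Of the fixed markers Gfap (0.65 ± 0.13), T (0.50 ± 0.11) and Pax6 (0.45 ± 0.10) rose. Pparg (-0.70 ± 0.18), Myh6 (-0.55 ± 0.06), Tnnt2 (-0.53 ± 0.13), Pecam1 (-0.49 ± 0.06), Nanog (-0.41 ± 0.05) and Col1a1 (-0.35 ± 0.09) fell. With 1 day left out Gfap, T, Pparg, Tnnt2, Col1a1 and Hand1 lost their call, and with days 4 and 28 alone, chosen after seeing the data, T turned to -0.11 and Pparg to 0.07. Germ cell genes fell in 10 of 12 cases (10 adjusted over the list alone), with Mael (-0.71 ± 0.08) and Dazl (-0.55 ± 0.07). Epithelial genes fell in 12 of 20 and rose in 1, with Cldn4 (-0.40 ± 0.04), and trophoblast genes in 4 of 13, with Hand1 (-0.62 ± 0.13). These 3 of 24 lists that passed held with an estimated correlation. Neuron genes rose in 21 of 26 cases and fell in 1 (adjusted p = 0.0968 with an estimated correlation) and pluripotency genes fell in 16 of 25 (adjusted p = 0.104 with an estimated correlation), with Klf2 at -0.39 ± 0.06, as examples of the other 21 (adjusted p = 0.0526 to 0.464 with an estimated correlation). In edgeR's test 2120 of 16482 genes passed, 1165 higher and 955 lower. The number was 1028 without the libraries of D12 and 789 without those of D18.

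At 100 nM Fam181b (gene ID 58238) rose 1.85-fold (log2 0.89 ± 0.11). It was followed by Foxb1 (0.88 ± 0.12), Dbx1 (0.86 ± 0.16), Pou4f1, a factor of sensory neurons (0.86 ± 0.14), Epha10 (0.85 ± 0.15), Cdh8 (0.84 ± 0.10), Nhlh1 (0.83 ± 0.09), Stmn3 (0.81 ± 0.11), Syt4 (0.81 ± 0.16) and Dpysl4 (0.81 ± 0.12). Adgrf5 fell 2.32-fold (log2 -1.22 ± 0.12). Next were Pax9 (-1.11 ± 0.16), Hand1, a factor of trophoblast and heart (-1.11 ± 0.10), and the transferrin gene Trf (-1.09 ± 0.13). They were followed by the water channel gene Aqp1 (-1.03 ± 0.09), the collagen gene Col6a3 (-0.99 ± 0.15), Eln (-0.94 ± 0.26), Tbx1 (-0.93 ± 0.18), Ttn (-0.92 ± 0.18) and Trp63 (-0.91 ± 0.13). Of the fixed markers Tubb3 (0.65 ± 0.11), Pax6 (0.61 ± 0.08) and Thra (0.13 ± 0.04) rose. Pparg (-0.85 ± 0.16), Afp, alpha-fetoprotein (-0.84 ± 0.12), Col1a1 (-0.63 ± 0.10), Myh6 (-0.49 ± 0.13) and Pecam1 (-0.46 ± 0.09) fell. Epithelial genes fell in 12 of 20 cases and rose in 1, with Krt19 (-0.47 ± 0.05). BMP and TGF-beta genes fell in 13 of 25 (15 adjusted over the list alone), with Tgfb1 (-0.47 ± 0.05). Cardiac genes fell in 8 of 24, with Tnni1 (-0.90 ± 0.11), and imprinted genes in 6 of 19 and rose in 2, with Igf2 (-0.49 ± 0.08). Trophoblast, endothelial, adipocyte, cartilage, FGF and retinoic acid, and estrogen-responsive lists also pointed down, with Krt7 (-0.77 ± 0.04), Cdh5 (-0.90 ± 0.11), Cebpa (-0.44 ± 0.09), Spp1 (-0.48 ± 0.08), Rarb (-0.81 ± 0.08) and Igf1 (-0.80 ± 0.14). These 10 of 29 lists that passed held with an estimated correlation. As examples of the other 19 (adjusted p = 0.0738 to 0.542 with an estimated correlation), neural progenitor genes rose in 17 of 22 cases (adjusted p = 0.0772 with an estimated correlation) and leukocyte genes fell in 7 of 18 (adjusted p = 0.169 with an estimated correlation), with Mrc1 at -1.24 ± 0.17. Leaving out 1 day ended the calls of Eln, Syt4, Thra and Myh6. At 100 nM 2415 of 16467 genes passed, 1205 of them higher. The number was 1231 without the libraries of D12 and 925 without those of D18.

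With both doses combined (10 TBBPA and 10 DMSO libraries over 5 days), Foxb1, a forkhead gene of the developing brain (gene ID 64290), rose 1.84-fold (log2 0.88 ± 0.09). Stmn3 (0.86 ± 0.10), Dbx1 (0.85 ± 0.12), Syt4 (0.85 ± 0.13), Nhlh1 (0.80 ± 0.09), Dpysl4 (0.80 ± 0.10), Fam181b (0.80 ± 0.10), Cdh8 (0.79 ± 0.09), Celf3 (0.79 ± 0.11) and Nkx6-2 (0.73 ± 0.12) rose as well. The falls were led by Adgrf5 (-1.22 ± 0.09), Rhox9 (-1.01 ± 0.11), Lgals3 (-0.91 ± 0.10), Arhgef6 (-0.91 ± 0.13), Pax9 (-0.90 ± 0.12), Zfp36l3 (-0.90 ± 0.15), Ttn (-0.88 ± 0.17), Hand1 (-0.86 ± 0.13), Pakap (-0.82 ± 0.10) and Aqp1 (-0.81 ± 0.07). Neuron genes rose in 24 of 26 cases (26 adjusted over the list alone) with adjusted p = 0.0654 with an estimated correlation, among them Elavl3 (0.72 ± 0.06) and Gap43 (0.62 ± 0.08). Epithelial, trophoblast, cardiac, BMP and TGF-beta, and cartilage genes fell in 16 of 20, 6 of 13, 14 of 24, 12 of 25 and 5 of 16 cases, with Perp (-0.37 ± 0.04), Krt7 (-0.71 ± 0.05), Actn2 (-0.76 ± 0.13), Bmp4 (-0.38 ± 0.06) and Alpl (-0.32 ± 0.06). Of these lists 1 epithelial gene and 2 BMP and TGF-beta genes rose. These 5 of 25 lists that passed held with an estimated correlation. The other 20 did not (adjusted p = 0.0516 to 0.542 with an estimated correlation).

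Fixed markers that rose were Tubb3 (0.70 ± 0.09), Pax6 (0.52 ± 0.08), Gfap (0.46 ± 0.12), T (0.41 ± 0.11) and Thra (0.13 ± 0.04). Pparg (-0.78 ± 0.14), Myh6 (-0.52 ± 0.10), Tnnt2 (-0.52 ± 0.13), Col1a1 (-0.49 ± 0.09), Pecam1 (-0.48 ± 0.07) and Nanog (-0.27 ± 0.07) fell. Hbb-bh1 passed as well, lower at 100 nM and with both doses, from a mean of 5.66 ± 10 to 2.95 ± 5.5 CPM over days that reached no count at D28. When 1 day was left out Gfap, T, Thra, Tnnt2, Nanog and Hbb-bh1 lost their call, and with days 4 and 28 alone T turned to -0.04 and Thra to -0.01. The dioxin-inducible Cyp1a1 (0.41 ± 0.24) and Cyp1b1 (-0.22 ± 0.08), the estrogen receptor gene Esr1 (-1.02 ± 0.37) and the thyroid hormone receptor gene Thrb (-0.14 ± 0.13) did not pass. Neither did Pou5f1 (-0.16 ± 0.08), Afp (-0.44 ± 0.17), Sox17 (0.21 ± 0.10) and Fgf10 (-0.03 ± 0.09). With DMSO, Cyp1a1 was at 1.47 CPM at D4 and 0.15 CPM at D28, and Esr1 at 0.0301 and 0.652 CPM. At such low levels not passing says little. Cyp1b1 had passed lower at D18 (-0.45 ± 0.10) and D28 (-0.42 ± 0.10), calls lost without 1 library. With both doses 3566 of 16242 genes passed, 1899 higher and 1667 lower, or 1436 and 1893 with library size alone as the scaling. The count was 1675 without the libraries of D12 and 1732 without those of D18.

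The 100 nM and 10 nM libraries were compared over the 5 days (n = 5 each) for the effect of dose. The smallest p belonged to Loxl2, a collagen crosslinking enzyme, with a log2 difference of -0.25 ± 0.04 (gene ID 94352; edgeR's adjusted p = 0.0695). Next were Plat, the tissue plasminogen activator, with -0.26 ± 0.04, Anxa5, annexin A5, with -0.27 ± 0.05, Msln, mesothelin, with -0.57 ± 0.10 and Ltf with -1.47 ± 0.28. None of them passed. None of the fixed markers passed either, and Afp was at -0.85 ± 0.24, Gfap at -0.42 ± 0.17, Nanog at 0.28 ± 0.10, Col1a1 at -0.27 ± 0.12, Tubb3 at -0.11 ± 0.12 and Myh6 at 0.07 ± 0.14. In edgeR's test 0 of 16242 genes passed, 1037 had an unadjusted p under 0.05, and DESeq2 called 8 and limma on log2(FPKM + 1) 2. Without the libraries of D4, D12 and D18 the count was 1, 4 and 1. Among the 3566 genes called with both doses together, the median absolute dose difference was 0.07 on the log2 scale, with a median 95% interval of ± 0.20. The median absolute effect of TBBPA was 0.26.

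With 20 lists camera passed although no member did, 6 of them higher and 14 lower at 100 nM, and fry passed 3 of the 20. BMP and TGF-beta genes pointed lower at 100 nM, with 0 of 25 members passing and 0 adjusted over the list alone, and of the 20 this list held (adjusted p = 0.0127 with an estimated correlation). Tgfb1 was at -0.21 ± 0.07 and Bmp2 at -0.32 ± 0.10. Among the other 19 (adjusted p = 0.0618 to 0.65 with an estimated correlation), 7 of 20 liver and yolk sac genes, such as Apoc2 (-0.61 ± 0.15), and 6 of 18 leukocyte genes, such as Mrc1 (-0.90 ± 0.22), passed adjusted over the list alone. Both pointed lower at 100 nM (adjusted p = 0.288 with an estimated correlation for either list).

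The effects of the doses correlated across genes with r = 0.686 and a covariance of 0.0361, where unchanged groups simulated against the same DMSO libraries gave 0.329 and 0.0063. With the DMSO libraries split between the doses r was 0.525 and 0.512 and the covariance 0.0306 and 0.0301. The difference from the simulated covariance was 0.0299. Both the split and the simulation treat the DMSO libraries of a day as independent. If these came from 1 culture, a deviation of that culture would still enter the effects of both doses, so such a shared control stays open. Of the genes called at both doses 631 were higher and 587 lower at both, and 0 went in opposite directions, a count that the shared DMSO libraries favour.

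**Figure D2:**
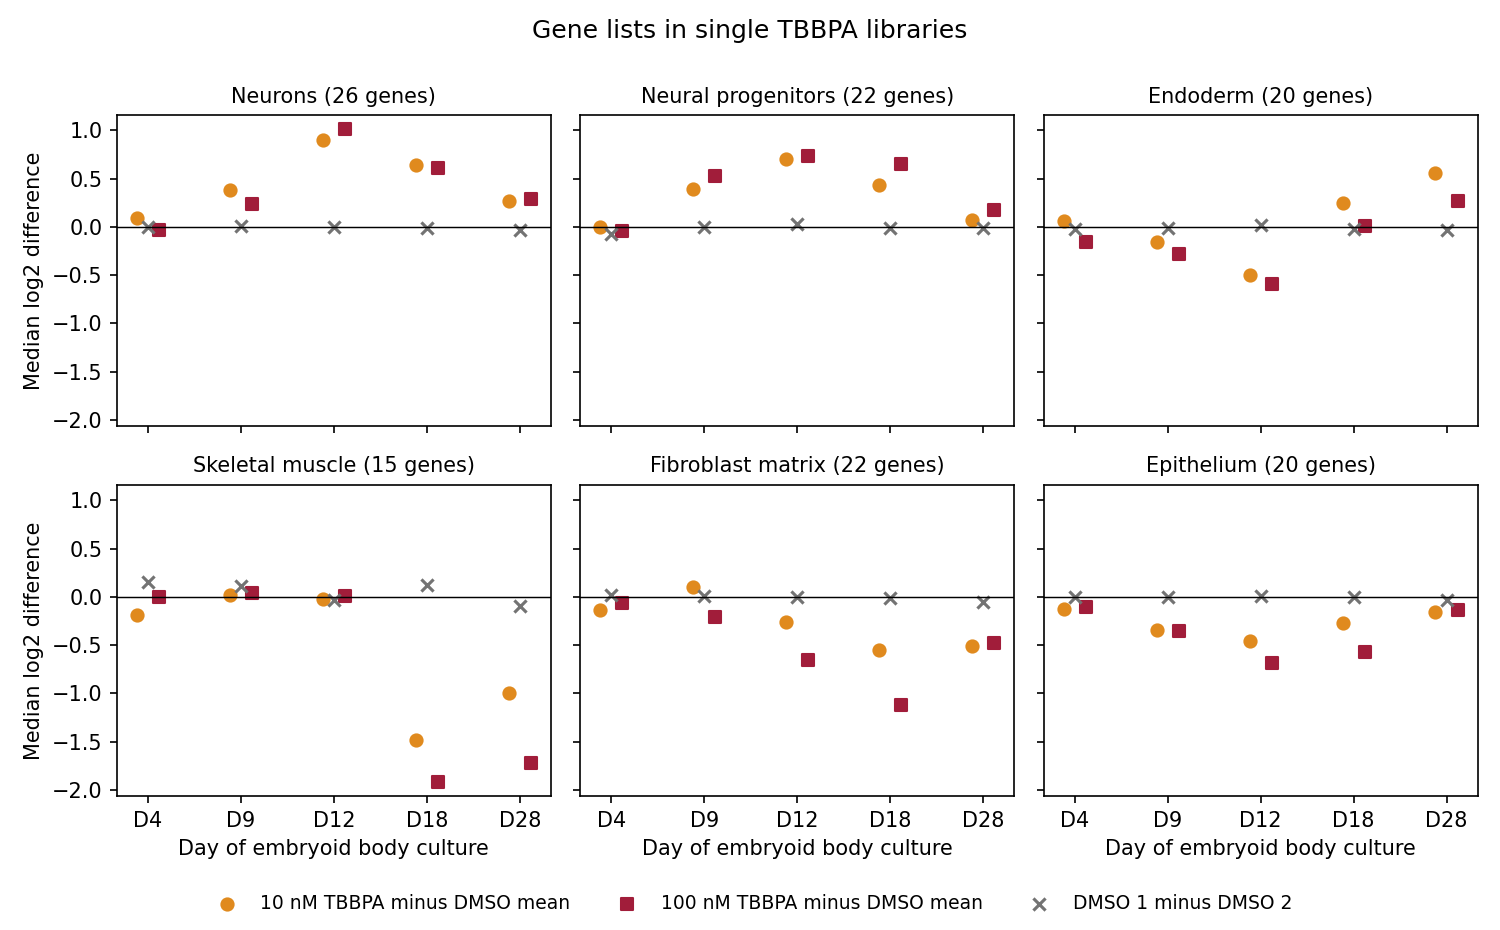
Median log2 difference between TBBPA and DMSO libraries for the genes of 6 lists (neurons, neural progenitors, definitive and visceral endoderm, skeletal muscle, fibroblast matrix, epithelium) against the day, 1 point for the 10 nM and 1 for the 100 nM library of each day. A grey cross marks the difference between the DMSO libraries of that day, and the neuron medians lie above 0 in 9 of 10 TBBPA libraries while the epithelial medians lie below 0 in 10 of 10.

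**Figure D3:**
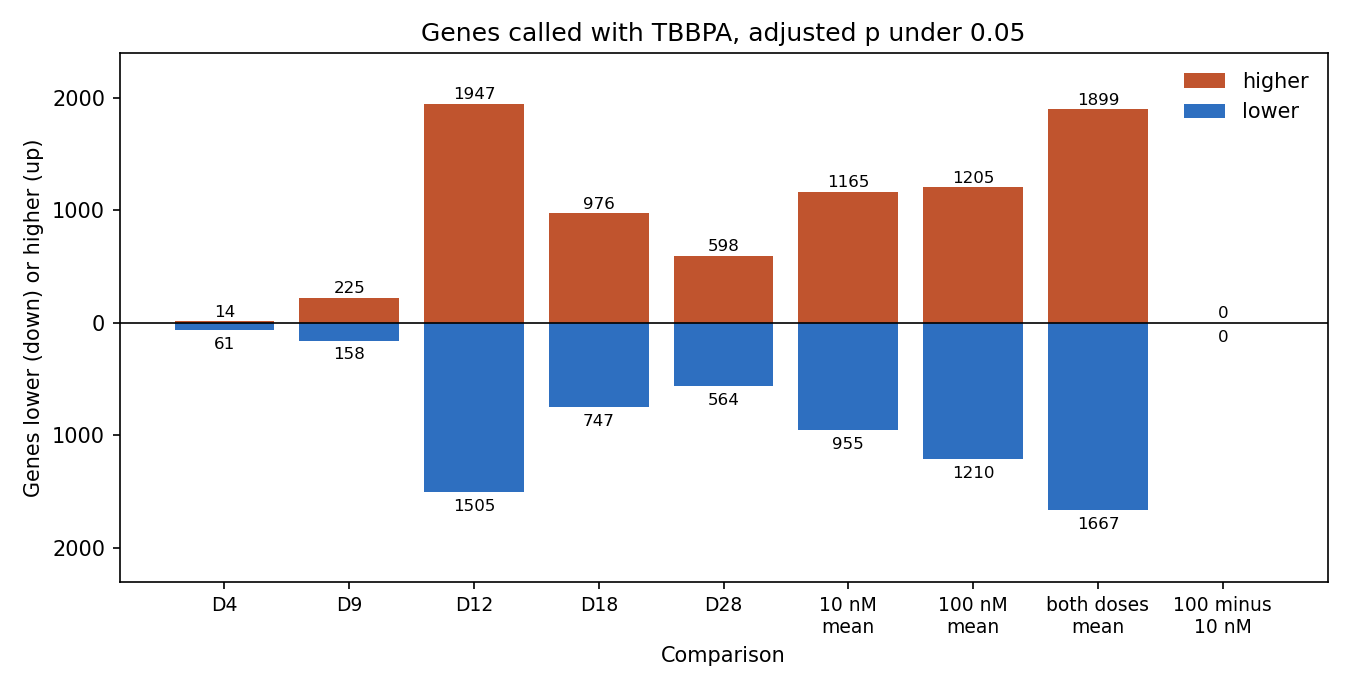
Number of genes higher (above 0) and lower (below 0) with TBBPA at each day and in each mean over days, as counts of genes at an adjusted p under 0.05 in edgeR's test. The largest count at a single day is that of D12, with 1947 higher and 1505 lower.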

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

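The tests of D28 against D12 for gene lists, the tests of explanations and the permutations of labels in this part were chosen after the results were seen.

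The effect of TBBPA differed between the days for 1708 genes in edgeR's test. With each DMSO pair summed, chosen after seeing the data, it did so for 21, and in simulated counts 13.5% of the calls of this test were genes not changed. Of the 118 genes named at a day, 76 were among them, a share favoured by naming genes for large effects at a day. Their adjusted p was lowest for Pga5 (1.88e-08), Dab2 (1.8e-06), Fgf15 (1.72e-05), Mylk (3.71e-05) and Pim2 (5.15e-05). It lay below 0.005 for Neurog2 (0.000123), Sox17 (0.000148), Hnf4a (0.00023), Gata4 (0.000246), Cdh1 (0.000343), Tfcp2l1 (0.000457), Btbd17 (0.000464), Fez1 (0.000497), Fzd1 (0.000513), Tnnt3 (0.000615), Cubn (0.000695), Map2 (0.000709), Rspo1 (0.0011), Actc1 (0.00116), Actn2 (0.00178), Fgf4 (0.00188), Stmn4 (0.00277), Celf3 (0.0028), Ogn (0.00283), Fn1 (0.003), Tal2 (0.003), Cdkn1a (0.00364), Sox2 (0.00366), Birc5 (0.00474) and Plet1 (0.0048). It was larger for Fgb (0.00532), Wnt1 (0.00534), Nefl (0.00539), Slc28a2 (0.00558), Rps23 (0.00704), Dll1 (0.00739), Lgals3 (0.00745), Ldha (0.00755), Cxcr4 (0.00885), Eomes (0.00886), Stmn3 (0.00906), S100g (0.00907), Ccnb1 (0.00956), Nkx6-2 (0.00961), Wnt8b (0.0112), Tubb3 (0.0122), Fabp7 (0.0122), Asic4 (0.0126), Hmox1 (0.0138), Zic1 (0.0149), Plk1 (0.0167), Nepn (0.0183), Nrp2 (0.019), Cyp1b1 (0.0191), Grhl2 (0.0194), Acta1 (0.0216), Dcc (0.0218), Meis3 (0.0236), Pecam1 (0.0239), Cartpt (0.0251), Bhlhe41 (0.0263), Tal1 (0.027), Fgf10 (0.0285), Gpr50 (0.0301), Vat1l (0.0301), Tdh (0.0307), Myh3 (0.0319), Ahr (0.0321), Atp2a1 (0.037), Foxa2 (0.038), Elavl3 (0.0388), Sox1 (0.0404), Slc1a2 (0.0409), Adgrf5 (0.0432), Arl14epl (0.046) and Dppa3 (0.0479). Between D12 and D28 the endoderm list and the list of S phase and mitosis moved up (adjusted p = 0.0233 each with an estimated correlation), and the lists of neural progenitors (0.0233), neurons (0.0276) and Notch and hedgehog signalling (0.0413) moved down.

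Neuron genes were higher with TBBPA at D12, with a median of 0.997 on the log2 scale, and the medians of the single libraries lay above 0 in 9 of 10. Embryoid bodies that were further along in time would also have higher fibroblast matrix genes, which rose from D9 to D18 in the controls. With TBBPA at D12 these had a median of -0.457 (interquartile range 0.337). This argues against a forward shift in time as the whole cause there. A partial shift stays open, since the effects at D12 correlated across genes with the control change from D9 to D18 (r = 0.219). Pluripotency and liver genes (medians of -0.606 and -0.793 with TBBPA) also fell in both. The correlation did not keep 1 sign over days and doses. At D18, with the control change from D12 to D28, r was -0.217 (-0.088 for 10 nM and -0.291 for 100 nM). At D9, with the change from D4 to D12, it was 0.215 for 10 nM and -0.066 for 100 nM. A difference in scaling or depth moves every list alike, and epithelial genes had a median of -0.557 (interquartile range 0.159) in the same libraries. A larger share of neural cells in the embryoid bodies, or more neuronal RNA per neural cell, stay open as explanations that may hold, since neither was tested.

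Endoderm genes were lower at D12 and higher at D28 with TBBPA, though neither list call held by itself with an estimated correlation (adjusted p = 0.113 and 0.0738). At D12 the median fell by at least 0.501 in both TBBPA libraries (interquartile range of the members 0.304 in that library), which argues against a single aberrant library there. At D28 the median rose in both TBBPA libraries, by 0.562 at 10 nM and 0.265 at 100 nM, while the DMSO pair differed by -0.033. The smaller shift lay within the interquartile range of the members, 0.437, and the DMSO pair may show technical spread only. A single aberrant library and a change in both therefore cannot be told apart at that day. Scaling or depth at D28 would raise every list, and skeletal muscle genes had a median of -1.33 (interquartile range 0.392) there. A real reversal with time and a difference between the cultures of these days stay open.

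The genes called at single days could also come from a difference between cultures unrelated to TBBPA. The ES libraries, which carry the same label, differed by a mean chi-square of 24.5 per gene, more than the 23 at most between DMSO and TBBPA libraries of a day, while the DMSO pairs differed by 3.61 at most. The labels do not say which libraries shared a culture, so exposure and culture cannot be told apart for these calls.

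Over the days, labels were permuted within each day. For 10 nM, 1 of 50 splits, the real one, called as many genes (2120, highest other 143). For 100 nM it was 1 of 50 (2415, highest other 53) and for both doses 1 of 50 (3566, highest other 1987). That other split kept 14 of 20 labels, with the doses counted as separate labels. The real split alone keeps the DMSO pair of every day together as controls, and these pairs differed little (mean chi-square 1.67 to 3.61). This closeness favours the real split whatever its cause. The counts thus argue only against libraries of a day that differ independently of their labels. These splits break up any culture shared by the libraries of a day, so they leave a difference between cultures open. For the dose difference the 16 possible splits are too few for a share under 0.05, with 0 genes called by edgeR for the real one (1037 at an unadjusted p under 0.05, 8 in DESeq2), 1 for the highest other, and as many or more in 16 of 16.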

How the results depend on the processing

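The settings chosen after seeing the data are listed in the methods, and the others were fixed before. The DMSO pairs differed little beyond counting noise, and each dose has 1 library at a day. Counts of calls are those of edgeR unless another tool is named, and the cause of a moved count was not tested except where fewer libraries enter a fit. Of 7830 values of the 503 named results that passed, 7099 kept direction and call over the alternatives, 727 lost the call and 4 changed sign. Of 389 values of the 25 named results that did not pass, 355 stayed so, 25 passed and 9 changed sign. Of 1120 values of the 280 list calls 875 held, 245 were lost and 0 changed direction. The number of list calls was 94 with an estimated correlation, 281 with DESeq2 size factors, 277 with library size alone and 322 with fry, which also counts lists that camera did not pass. Of the lists passed by camera, fry passed all in the control steps, 1 of 7 at D4, 10 of 18 at D9, 23 of 24 at D12, 14 of 17 at D18, 14 of 20 at D28, 20 of 24 for 10 nM, 24 of 29 for 100 nM, 24 of 25 for both doses and 3 of 20 for the dose difference.

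Leaving out 1 library gave 8804 to 10759 genes from ES cells to D4, 8372 to 8560 from D4 to D9, 3236 to 3426 from D9 to D12, 4141 to 4216 from D12 to D18 and 6707 to 6805 from D18 to D28. With TBBPA it gave 1 to 29 at D4, 93 to 287 at D9, 1718 to 2170 at D12, 735 to 1342 at D18, 231 to 1303 at D28 and 1015 to 3356 for the difference between days. Leaving out 1 day gave 789 to 2359 for 10 nM, 925 to 2582 for 100 nM, 1675 to 3628 for both doses and 0 to 4 for the dose difference, and leaving out day 12 or day 28 gave 515 and 723 for the difference between days. The named genes that lost their call without 1 library or day were Tnnt2 from D12 to D18, Hbb-bh1 and Pparg from D18 to D28, Cyp1a1 from D4 to D9, Afp, Fgf10 and Pecam1 from D9 to D12, and Cyp1a1, Pparg, T and Tnnt2 from ES cells to D4. With TBBPA they were 16 of 17 at D4, all but Pim2, 16 of 24 at D9, 5 of 40 at D12, 9 of 33 at D18 and 10 of 25 at D28, and 6 of 34 for 10 nM, 4 of 39 for 100 nM and 6 of 39 for both doses. In 1 or more of the other settings the call was lost by 17 at D4, 24 at D9, 7 at D12, 13 at D18 and 24 at D28, all of these with each DMSO pair summed, and by all 34, 39 and 39 for 10 nM, 100 nM and both doses, all of these without a day term.

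With the replicate number as a block the steps gave 10006, 9779, 5240, 6034 and 8479 genes in the order of time, of which 9945, 9703, 5163, 5926 and 8397 were also called without the block. Over 15 pairs of control groups the deviations of libraries with the same number correlated across genes by -0.036 to 0.057, so no pairing was seen. Much of these deviations may be counting noise, so the check cannot exclude that the numbers pair the samples. No analysis paired by replicate number was possible for TBBPA because each dose has 1 library at a day, while the means over days and the dose difference compare libraries within days.

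With the compared libraries alone in the fit 8056 genes passed from D9 to D12, and with TBBPA 663 at D4, 576 at D9 and 5223 at D12. The 10 nM library alone, assumed to vary like the controls, gave 4 at D4, 217 at D9, 1894 at D12, 951 at D18 and 429 at D28. DESeq2 gave 160 at D4 and 8 for the dose difference. On log2(FPKM + 0.1) limma gave 142 at D4, 193 at D9, 1043 at D18, 639 at D28 and 1280 for 10 nM, and on log2(FPKM + 1) 1364 for 10 nM and 2 for the dose difference. Without the ES libraries the counts were 269 at D4, 771 at D9, 2600 at D18, 2074 at D28 and 3380 for the difference between days. With each DMSO pair summed they were 0 at D4 (694 at an unadjusted p under 0.05), 0 at D9 (918), 781 at D12, 172 at D18, 6 at D28, 21 between days, 277 for 10 nM, 130 for 100 nM and 1231 for both doses. With DMSO library 1 or 2 alone they were 286 and 263 for 10 nM, 145 and 151 for 100 nM, and 1138 and 1199 for both doses. Without a day term edgeR called 0 genes for 10 nM, 100 nM and both doses (85, 131 and 222 at an unadjusted p under 0.05), since the differences between days then enter the spread. Days 4 and 28 alone gave 439 for 10 nM, 477 for 100 nM, 602 for both doses and 2 for the dose difference.

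With days 4 and 28 alone the log2 change turned for 10 nM in Pparg (0.07) and T (-0.11), for both doses in T (-0.04), Thra (-0.01), Cyp1a1 (-0.10), Fgf10 (0.32) and Pou5f1 (0.09), and for the dose difference in Col1a1 (0.11) and Tgfb1 (0.02). Leaving out 1 day, Fgf10 for both doses ran from -0.14 without D28 to 0.09 without D12 (0.02 without D9), and Myh6 in the dose difference from -0.13 without D28 to 0.16 without D18, and was at -0.15 with days 9, 12 and 18 alone.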

Other observations

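The genes of the first paragraph were chosen after their values were seen, and no test beyond those of the report was added.

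Of 4792 genes that passed with TBBPA at 1 day or more, 297 did so in the same direction at 3 days or more and 32 at 4 days, while 0 did so at all 5 in edgeR's test and 245 passed in opposite directions at 2 days. Most of the 32 were lower with TBBPA, among them Prl2c5 (-1.86 at D12), Ctsj (-1.92) and Fnd3c2 (-1.69). Some others are named here, and the 32 were not tested for a shared function. Lgals3, a galectin, was at -1.28 ± 0.14 at D12 and Krt7, a keratin of simple epithelium, at -0.71 ± 0.11. The neuronal RNA-binding gene Elavl3 was at 1.03 ± 0.09 at D12 and Fez1, an axonal transport adaptor, at 1.09 ± 0.09. The nicotinic receptor gene Chrna4 was at 0.99 ± 0.11 and the neural tube homeobox gene Nkx6-2 at 1.25 ± 0.15. At D4 Fez1 was at -0.62 and Nkx6-2 at -0.45, and neither passed there.

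Averaged over the days, oxidative phosphorylation genes had a median log2 change of 0.056 with both doses, with 4 of 22 members higher, and cholesterol synthesis genes 0.071, with 3 of 22 higher. Camera passed both lists with the preset correlation (adjusted p = 0.0038 and 0.0117) and neither with an estimated one (0.423 and 0.412). Camera passed the thyroid hormone axis in 0 of 14 comparisons, with 2 at an unadjusted p under 0.05, while fry passed it in 6. Its lowest adjusted p in camera's test was 0.0691, for TBBPA at D12. Replication-dependent histones, with 4 or 7 measured members, passed in 0 of 14 as well (0 at an unadjusted p under 0.05, 1 with fry), with a lowest adjusted p of 0.359.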
